A study of Mus musculus with 4 samples.

How the data were processed

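Total RNA from the hippocampus of Tas1r3 knockout and wild-type mice on a western diet was sequenced in 4 libraries, 2 per genotype. Libraries were prepared with an Ion Total RNA-Seq kit, per the labels' protocols. The submitters' processing notes name STAR, Partek and the mouse build mm39, without versions. The transcript annotation release, the quantification model, the normalization method and the use of read strand are not given in the sources used here.

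For each library the authors deposited a table of normalized signal per RefSeq transcript, with the same 30108 transcripts in every table. Each library was scaled by the authors to nearly the same total, 2.99e+06 units. A constant of 0.0001 appears to have been added to every deposited value, and no transcript was at 0 in any library. The low values pile up at multiples of one step per library, which is what 1 read is worth. The step was 0.258 units in WT-WD replicate 1, 0.187 in WT-WD replicate 2, 0.222 in KO-WD replicate 1 and 0.231 in KO-WD replicate 2. It gives estimated depths of 11595994, 15959716, 13510773 and 12941979 reads, in the same order. Of the transcripts below 20 reads, between 16.1% and 22.7% were whole multiples of the step within 0.02 read. Whole reads could therefore not be recovered for most transcripts and no count model was used. A floor of 3 reads corresponds to between 0.562 and 0.775 units, and covers counting error only.

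The constant was subtracted, and the transcripts of each gene were summed. Gene symbols were taken from a RefSeq gene table of the assembly GRCm38.p6, which matched 30073 transcripts. The remaining 35 kept their transcript identifier. Because that assembly is not the authors' build, it was used only for names, for the chromosome and for the order of neighbouring genes, and no coordinates are given. Summing gave 16148 genes. Genes with at least 1 unit in at least 2 libraries were kept, which left 15707. Values were transformed to log2(value + 1), so fold changes are on that scale and understate the change of genes with low signal.

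The design fixed before the data were examined had one test for counts and another for normalized values. The deposited unit called for the second. KO-WD was compared with WT-WD in limma 3.58.1 (R 4.3.3), with an intensity trend and robust empirical Bayes moderation, 2 residual degrees of freedom and genotype as the only term. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. All gene-wise and adjusted p-values below come from limma and are two-sided. The choices made before the data were examined are the groups, this test, the filter, the pseudocount, the gene lists, the rule for named genes and the alternatives listed as fixed beforehand.

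Gene lists for signalling pathways, cell types, neighbouring brain regions and the surroundings of the targeted gene were fixed before the data were examined. The 46 lists with at least 3 tested members were tested with limma's camera with an intensity trend at a preset correlation of 0.01 between genes, with camera using an estimated correlation, and with fry. With an estimated correlation, camera also falls back on the 2 residual degrees of freedom of the fit, which leaves it little power. Its result therefore differs from the preset one in more than the correlation. Adjusted p-values of lists are Benjamini-Hochberg values over the 46 lists. For members of a list, limma p-values were also adjusted over the list alone.

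The genes named follow a rule fixed in the design. They are Tas1r3 and the other detected taste signalling genes, and up to 12 rising and 12 falling genes with the largest change among those past the threshold. These had to average at least 1 unit, to have no overlap between the genotypes and to carry a symbol other than a predicted name. Where fewer than 8 qualified in a direction, genes with the smallest unadjusted p filled up to 8 and are reported as not passing. In each list described, the 2 to 4 members with the smallest unadjusted p are named, with members given as background. Genes the rule picks that are not used here are left out without a replacement. Named outside the rule, after their values were seen, are the 4 called genes with predicted names, the neighbours of Tas1r3 with small p-values, genes named because they overlap a called gene or Tas1r3, Clic6, Mal, Ddx3y and Snhg11.

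Alternatives fixed beforehand were quantile normalization, no filter, a filter at 5 units, limma without trend or robust moderation, pseudocounts of 0.1 and 0.5, the replicate number as a block, other thresholds, an estimated correlation for the lists and leaving out each library in turn. Alternatives added after seeing the data were the sum of coding transcripts alone, median-ratio scaling, precision weights from the estimated reads (limma's voom) and a test of each transcript alone.

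The limma fit was tested on simulated data drawn for the genes and libraries used here, in 5 runs with 200 changed genes among about 15715 tested. It recovered 60.2% of the genes changed 2-fold and 87.3% of those changed 4-fold, none in the wrong direction, and called 11.4 unchanged genes per run. Both the recovery and the unchanged genes called depend on how many genes change, 200 in these runs against 10 called in the data. They therefore do not carry over to the data. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.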

Results

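The series asked how the sweet and umami taste receptor subunit encoded by Tas1r3 bears on the hippocampus of mice made obese by diet. Hippocampal RNA was sequenced from wild-type mice (WT-WD, n = 2 libraries) and Tas1r3 knockout mice (KO-WD, n = 2 libraries), all fed a western diet, a chow rich in fat and sugar, for 18 weeks. The comparison of KO-WD with WT-WD therefore describes the genotype on 1 diet, and a control diet was not analysed here. Values are the deposited normalized signal, summed over the transcripts of each gene, and means are given with the SD of 2 libraries. Estimated depth was 11595994 and 15959716 reads in the WT-WD libraries and 13510773 and 12941979 reads in the KO-WD libraries. The labels do not say that the libraries came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

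Tas1r3, the targeted gene on chromosome 4 (NM_031872), was low in wild-type hippocampus and nearly absent in the knockout. Its signal was 16.1 and 15.9 units in the WT-WD libraries, from an estimated 62.5 and 85.0 reads, against 0.887 and 1.85 units in the KO-WD libraries, from an estimated 4 and 8.01 reads. Each library carried the level its genotype label calls for. The log2 difference was -2.88 (SE 0.34), 7.34-fold lower in KO-WD. Its adjusted p of 0.0813 in limma missed the threshold over all genes (between 0.00942 and 0.537 under the alternatives tried), while adjusted over the list alone, the taste signalling genes, it was 0.000342. The span of Tas1r3 overlaps that of the far more abundant Dvl1 in the GRCm38.p6 gene table, so reads of either gene could reach the other if strand was not used.

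Of the 12 genes in the taste signalling list 6 were tested, Tas1r3 among them, and the rest were not measured or fell under the filter. The other taste signalling genes tested in hippocampus were the partner receptor subunit Tas1r1 and the downstream genes Plcb2, Itpr3, Trpm4 and Gng13. None of them passed the test. Tas1r1 averaged 6.56 ± 2.66 units in WT-WD and 8.03 ± 0.87 in KO-WD. Plcb2, the phospholipase of the taste cascade, averaged 7.69 ± 1.07 and 4.71 ± 2.03 units (log2 difference -0.65, SE 0.36). Itpr3, the calcium release channel of the cascade, averaged 13.2 ± 3.98 and 11.4 ± 1.75 units. Trpm4 averaged 16.9 ± 2.69 and 18.1 ± 0.05 units, and the G protein subunit Gng13 averaged 62.3 ± 8.04 and 54.4 ± 17.1 units. Of the 6 tested members of this list, 1 fell when adjusted over the list alone (Tas1r3) and 0 over all genes. The list test gave adjusted p = 0.082, and adjusted p = 0.618 with an estimated correlation.

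Across the hippocampal transcriptome few genes separated the genotypes. Of 15707 genes tested, 8 rose and 2 fell in KO-WD past the adjusted threshold in limma. Of these 10, 5 lie on chromosome 4 with Tas1r3, and 2 of those lie within 50 tested genes of it. The named genes that rose were Mfap2, Cptp, Tmem208, Zranb1 and Ndc1, and the named gene that fell was Nfxl1. At an unadjusted p under 0.05 there were 829 genes, 374 higher and 455 lower in KO-WD, where chance gives 785. The genotypes did not overlap for 36.3% of genes, against 33.3% by chance. The same held for all 10 called genes, which a call with 2 libraries per genotype nearly ensures.

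Cptp, the immediate neighbour of Tas1r3 and the carrier of ceramide-1-phosphate between membranes, rose from 7.48 ± 0.36 to 40.9 ± 5.48 units (log2 2.30, SE 0.23, adjusted p = 0.0272). Mfap2, a protein of extracellular microfibrils, rose from 8.58 ± 3.78 to 169.5 ± 25.0 units (log2 4.20, SE 0.30, adjusted p = 0.0198). Ndc1, a membrane component of the nuclear pore, rose 2.90-fold, from 130.7 ± 7.54 to 381.5 ± 30.1 units (adjusted p = 0.0143). All 3 lie on chromosome 4, Mfap2 163 and Ndc1 558 tested genes from Tas1r3. Tmem208, a membrane protein of the endoplasmic reticulum, rose 4.39-fold (adjusted p = 0.0272), and Zranb1, a deubiquitinase, rose 2.94-fold (adjusted p = 0.0272). Nfxl1, a zinc finger protein, fell 5.93-fold, from 599.9 ± 50.3 to 101.1 ± 19.99 units (adjusted p = 0.00527).

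The other 4 called genes are non-coding and carry predicted names. Gm16008, which lies 10 tested genes from Tas1r3 on chromosome 4, rose from 104.7 ± 13.6 to 890.5 ± 90.0 units (log2 3.08, SE 0.13, adjusted p = 0.000835), the smallest p-value of all tested genes. Its span overlaps Tnfrsf18 in the gene table. Gm42303, on chromosome 4 but 649 tested genes from Tas1r3 and overlapping Ptprd, rose 2.71-fold. Gm16835, which overlaps Uggt2, rose 2.24-fold. Gm36445 fell, from 271.2 ± 17.2 to 108.6 ± 10.6 units.

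**Figure D1:**
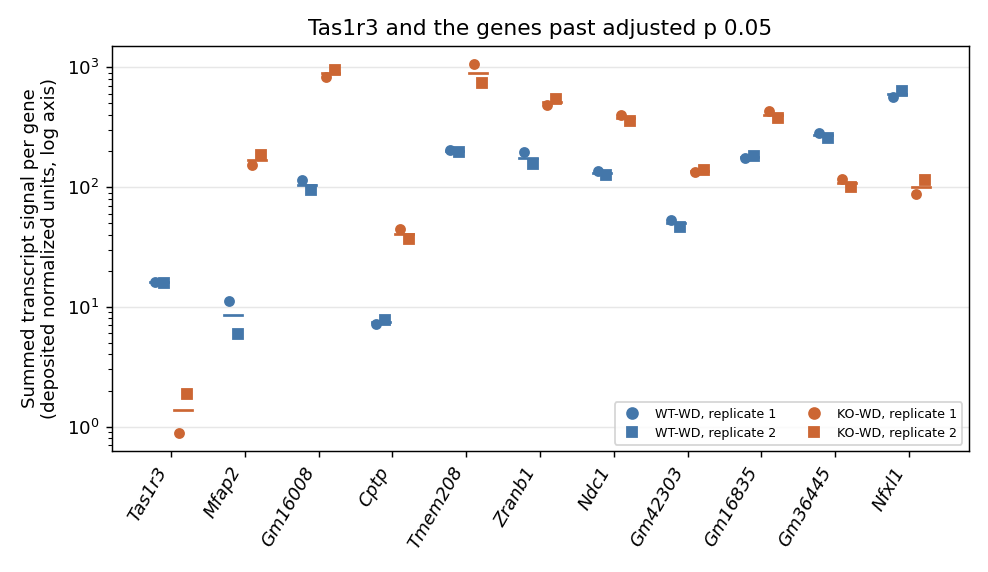
Summed transcript signal per gene in deposited normalized units on a log axis, for Tas1r3 and the 10 genes past adjusted p 0.05. Points are the 4 libraries, by genotype and replicate, and bars are the means of 2 libraries. Tas1r3 sits at 16.1 and 15.9 units in WT-WD and at 0.887 and 1.85 in KO-WD, and the genotypes do not overlap for any gene shown.

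In all 5 called coding genes other than Cptp, the change lay in a transcript that RefSeq lists as non-coding, and the coding transcripts did not follow. The non-coding transcript of Mfap2 rose from a mean of 5.42 to 167.1 units, while its coding transcripts together gave 3.16 and 2.43. The non-coding transcript of Nfxl1 fell from 597.2 to 90.4 units, while the coding one was at 2.69 and 10.7. For Ndc1 the non-coding transcript went from 104.4 to 362.1 units and the coding one from 26.3 to 19.4. For Zranb1 the non-coding transcript averaged 27.5 and 393.2 units, with 54.4 and 0.527 in the WT-WD libraries, and the coding ones together 148.3 and 122.5. Non-coding transcripts held between 34.9% and 35.2% of the signal of each library. With coding transcripts alone, limma called 1 of 14596 genes, Cptp (adjusted p = 0.043). There, 918 genes had an unadjusted p under 0.05, against 829 of 15707 in the main fit. The calls fell in number, but the small unadjusted p-values did not. When each of the 29293 transcripts was tested alone, limma called 0, with 1668 at an unadjusted p under 0.05.

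The genes with the next smallest p-values did not pass. Mpc1, a subunit of the mitochondrial pyruvate carrier, averaged 328.9 ± 49.5 units in WT-WD and 152.6 ± 0.34 in KO-WD (adjusted p = 0.0822). Htd2, an enzyme of mitochondrial fatty acid synthesis, averaged 27.2 ± 5.61 and 7.68 ± 0.82 units (adjusted p = 0.189). Trap1, the mitochondrial heat shock protein of the Hsp90 family, averaged 1063 ± 362 and 237.4 ± 19.2 units (adjusted p = 0.302), with the difference in its non-coding transcript. Oxr1, an oxidation resistance protein, averaged 3393 ± 44.4 and 2137 ± 157 units (adjusted p = 0.27). Hspa5, the main chaperone of the endoplasmic reticulum, averaged 607.9 ± 91.4 and 358.5 ± 17.1 units (adjusted p = 0.302). On the higher side, F5, coagulation factor V, averaged 58.8 ± 9.94 units in WT-WD and 153.0 ± 28.0 in KO-WD (adjusted p = 0.124). The zinc finger gene Zfat and the JmjC-domain gene Jmjd6 had log2 differences of 0.95 and 0.89 (adjusted p = 0.117 and 0.124). The difference of Mpc1, Oxr1, Zfat and Jmjd6 also lay mostly in non-coding transcripts, whereas Htd2, Hspa5 and F5 have coding transcripts alone. When 1 library was left out, some of these genes passed in limma. They were Trap1 without WT-WD replicate 1 (adjusted p = 0.0322) or 2 (0.0105), F5 (0.0441 and 0.0123), Mpc1 (0.0262 and 0.0306) and Jmjd6 (0.0441 and 0.0264) without KO-WD replicate 1 or 2, and Zfat (0.0307) and Htd2 (0.0489) without KO-WD replicate 1.

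The count of 10 genes depended on which libraries entered the fit. It was 24 without WT-WD replicate 1, 18 without WT-WD replicate 2, 93 without KO-WD replicate 1 and 74 without KO-WD replicate 2, with the lone library of a genotype assumed to vary like the others. Limma without trend or robust moderation called 0 genes, with 951 at an unadjusted p under 0.05.

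The surroundings of Tas1r3 on chromosome 4 held more small p-values than other chromosomes. Of the 72 tested genes within 50 places of Tas1r3, 13 had an unadjusted p under 0.05 (18.1%), 11 higher and 2 lower in KO-WD, against 756 of 14694 genes on other chromosomes (5.14%, Fisher's exact test, two-sided, p = 7.66e-05). The Fisher tests on this chromosome count genes as independent units, but neighbours were measured in the same 4 libraries. Their p-values therefore do not measure the spread between animals. Cptp and Gm16008 passed over all genes. Among those that did not, C1qtnf12, a secreted C1q and TNF related protein, averaged 8.74 ± 3.34 units in WT-WD and 27.4 ± 6.40 in KO-WD. Samd11 averaged 16.5 ± 2.81 and 3.59 ± 2.25 units, Morn1 12.1 ± 1.93 and 24.6 ± 4.52, and Agrn, the organizer of neuromuscular and other synapses, 366.4 ± 4.39 and 452.5 ± 50.6. On the rest of chromosome 4, 51 of 907 genes had an unadjusted p under 0.05 (5.62%, Fisher's exact test, two-sided, p = 0.536). Of these 907 genes, 3 passed over all genes (Mfap2, Ndc1 and Gm42303), against 5 of the 14694 on other chromosomes. Of the 42 tested genes in the list of Tas1r3 neighbours, 1 rose (Cptp) and 1 fell (Samd11) when adjusted over the list alone, and 1 passed over all genes. Fry's test for change in either direction passed for this list (adjusted p = 0.0124), while camera, which asks for 1 direction, did not (adjusted p = 0.466). The list's median was just under 0 and its mean was 0.07.

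**Figure D2:**
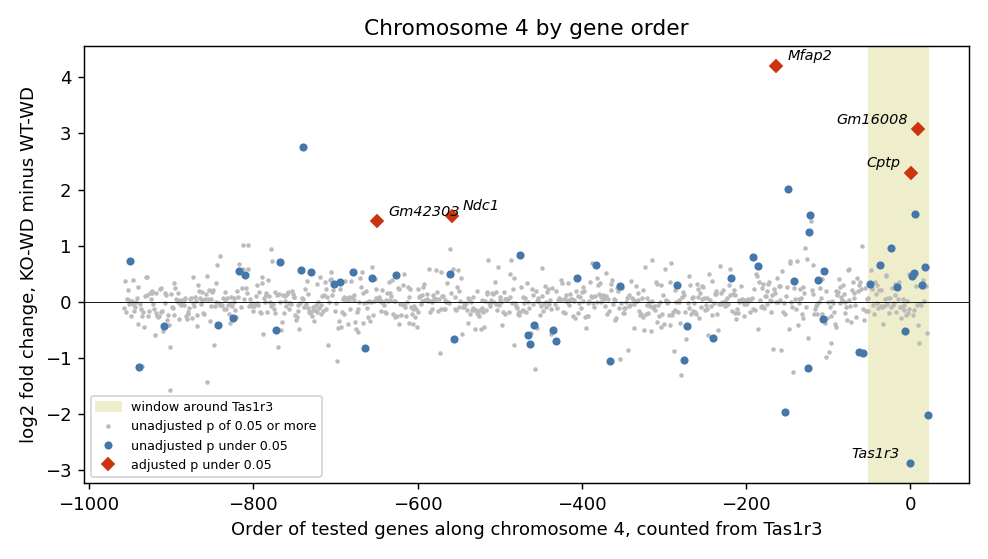
Log2 fold change of KO-WD minus WT-WD for each tested gene on chromosome 4 (y axis) by its order along the chromosome counted from Tas1r3 (x axis). Diamonds are the 5 genes past adjusted p 0.05, filled circles genes with unadjusted p under 0.05, and the shaded band is the window of up to 50 tested genes on each side of Tas1r3, in which 13 of 72 genes had an unadjusted p under 0.05.

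Markers of the choroid plexus, the tissue that secretes cerebrospinal fluid and borders the hippocampus, were higher in KO-WD. Of 19 markers, 18 were higher, and both KO-WD libraries lay above both WT-WD libraries in 11, where chance gives 16.7% for a single gene. The markers move together (estimated correlation 0.734), so they do not count as separate genes. F5 averaged 58.8 ± 9.94 units in WT-WD and 153.0 ± 28.0 in KO-WD, Otx2, a transcription factor of the choroid plexus, 15.3 ± 1.90 and 41.3 ± 14.0, the prolactin receptor Prlr 22.8 ± 9.85 and 57.1 ± 2.89, and Kl (klotho) 66.8 ± 22.0 and 124.1 ± 14.6. Ttr, the transthyretin that marks this tissue, was at 3212 and 1223 units in the WT-WD libraries and 6440 and 3078 in the KO-WD libraries. F5, Otx2, Prlr, Kl and Clic6 passed when adjusted over the list alone, and 0 passed over all genes in the main fit. F5 did pass over all genes when either KO-WD library was left out. With the replicate number as a block, F5 and Ttr passed. The list median was a log2 difference of 0.97 (camera, adjusted p = 6.85e-12), with adjusted p = 0.618 with an estimated correlation. Leaving out 1 library moved the median between 0.53 (without WT-WD replicate 2) and 1.31 (without WT-WD replicate 1). It was 0.65 without KO-WD replicate 1.

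**Figure D3:**
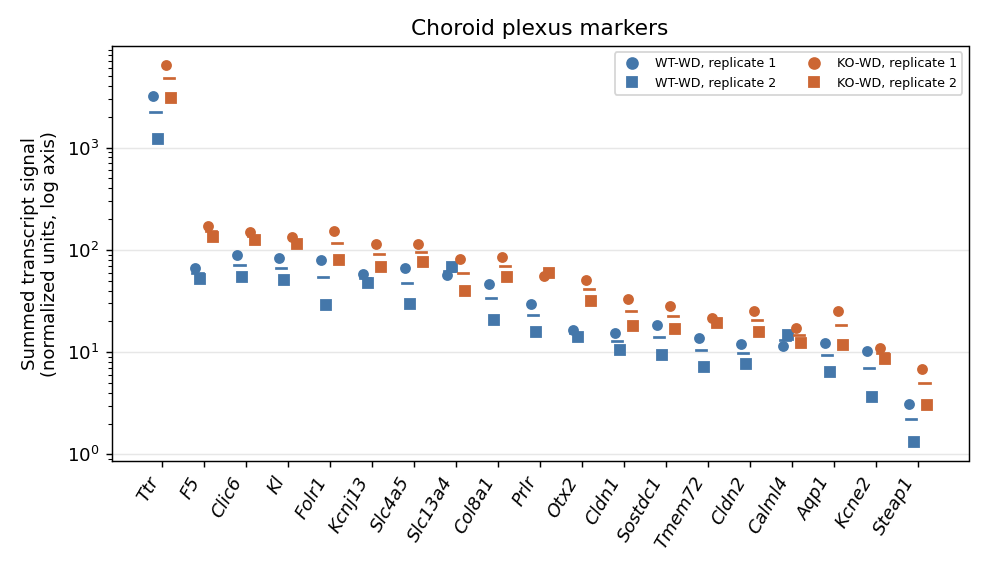
Summed transcript signal in deposited normalized units on a log axis for the choroid plexus markers. Points are the 4 libraries, by genotype and replicate, and bars are the means of 2 libraries. In 11 of 19 choroid plexus markers both KO-WD libraries lie above both WT-WD libraries.

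Markers of oligodendrocytes and myelin were lower in KO-WD. Of 18 members, 15 were lower, with a list median of -0.39 on the log2 scale (camera, adjusted p = 2.98e-05, and adjusted p = 0.618 with an estimated correlation). Adjusted over the list alone, 4 fell and 1 rose, and 0 passed over all genes. Mag, the myelin-associated glycoprotein, averaged 599.0 ± 37.4 units in WT-WD and 438.8 ± 1.07 in KO-WD, and Ermn and Mal had log2 differences of -0.64 and -0.41. The member that rose was Enpp2 (autotaxin), also a strong choroid plexus transcript, at 1607 ± 431 and 3074 ± 603 units. Oligodendrocyte precursor markers had a median of -0.15 (adjusted p = 0.0488, and adjusted p = 0.618 with an estimated correlation). The call was lost without WT-WD replicate 1 (median -0.30, adjusted p = 0.166), without WT-WD replicate 2 (median -0.0923, adjusted p = 0.19) and without KO-WD replicate 1 (median -0.12, adjusted p = 0.305). The median was -0.23 without KO-WD replicate 2. In that list Bcas1 and Olig1 fell adjusted over the list alone, with log2 differences of -0.52 and -0.44, and 0 passed over all genes.

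Chaperones of the endoplasmic reticulum and the cytosol were lower in KO-WD. Of 21 genes of the endoplasmic reticulum stress list, 19 were lower, with a median of -0.22 (camera, adjusted p = 2.99e-05, and adjusted p = 0.618 with an estimated correlation). The median was -0.36 without WT-WD replicate 1. Hspa5 and the calcium-binding chaperone Calr, at 603.4 ± 47.8 units in WT-WD and 440.2 ± 21.2 in KO-WD, fell adjusted over the list alone, and 0 passed over all genes. Hsp90b1 and Pdia6, a chaperone and a disulfide isomerase, had log2 differences of -0.41 and -0.40. Of 14 heat shock proteins, 11 were lower (median -0.18, adjusted p = 0.00536, and adjusted p = 0.618 with an estimated correlation). Without WT-WD replicate 2 the list no longer passed (median -0.11, adjusted p = 0.161). None passed adjusted over the list alone or over all genes, and the lowest p-values were those of Cryab (log2 -0.65, SE 0.18) and Dnaja1 (log2 -0.41, SE 0.12). Of 82 cytosolic ribosomal proteins, 69 were lower by a small margin (median -0.18, adjusted p = 8.67e-08, and adjusted p = 0.694 with an estimated correlation). 0 of them passed adjusted over the list alone or over all genes, and Rpl26 and Rps10 had log2 differences of -0.42 and -0.40. Without KO-WD replicate 2 the ribosomal list no longer passed (median -0.039, adjusted p = 0.471). Its median was -0.0899 without WT-WD replicate 2 and -0.30 without KO-WD replicate 1.

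Astrocyte, microglia, complement, pericyte, meningeal and red blood cell lists sat lower in KO-WD, and each lost its call without WT-WD replicate 2 and again without KO-WD replicate 2. Among 16 astrocyte markers 14 were lower (median -0.14, adjusted p = 0.00453, and adjusted p = 0.618 with an estimated correlation). The median was -0.0592 without WT-WD replicate 2 (adjusted p = 0.184), -0.0759 without KO-WD replicate 2 (adjusted p = 0.119) and -0.22 without WT-WD replicate 1. The water channel Aqp4 fell when adjusted over the list alone, from 296.7 ± 2.06 to 200.3 ± 15.4 units, and Gfap averaged 1003 ± 108 and 756.9 ± 1.47 units. Among 14 microglia markers 10 were lower (median -0.24, adjusted p = 0.0309, and adjusted p = 0.618 with an estimated correlation). Their median was -0.0437 without WT-WD replicate 2 (adjusted p = 0.276) and -0.18 without KO-WD replicate 2 (adjusted p = 0.178). Fcrls and Olfml3 fell adjusted over the list alone, by 0.88 and 0.86 on the log2 scale, and the list passed fry's test for change in either direction (adjusted p = 0.0419). Among 20 complement and phagocytosis genes 16 were lower (median -0.19, adjusted p = 0.00453, and adjusted p = 0.618 with an estimated correlation). Their median was -0.14 without WT-WD replicate 2 (adjusted p = 0.396), -0.19 without KO-WD replicate 2 (adjusted p = 0.0769) and -0.33 without WT-WD replicate 1. Apoe, the main lipid carrier of the brain, averaged 6105 ± 628 and 4481 ± 376 units, and C1qc had a log2 difference of -0.30.

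Pericyte and smooth muscle markers had a median of -0.40 (adjusted p = 0.00769, and adjusted p = 0.618 with an estimated correlation), with Myh11 at -0.56 and Rgs5 at -0.44. The pericyte median was -0.19 without WT-WD replicate 2 (adjusted p = 0.276), -0.32 without KO-WD replicate 2 (adjusted p = 0.142) and -0.62 without WT-WD replicate 1. Endothelium and blood-brain barrier markers did not pass (21 members, 7 higher and 14 lower, median -0.15, adjusted p = 0.125), with the glucose transporter Slc2a1 at -0.41 and the cadherin Cdh5 at -0.69. Meningeal fibroblast markers had a median of -0.46 (adjusted p = 0.00892, and adjusted p = 0.694 with an estimated correlation), with Slc6a13 at -0.92 and Lum at -0.76. Their median was -0.0767 without WT-WD replicate 2 (adjusted p = 0.907) and -0.11 without KO-WD replicate 2 (adjusted p = 0.989), but -0.80 without WT-WD replicate 1 and -0.96 without KO-WD replicate 1. Replicate 1 lay 0.76 below replicate 2 in WT-WD and 0.80 above it in KO-WD by the list's median, a wider gap than that between genotypes. Red blood cell genes had a median of -0.46 (adjusted p = 0.0265, and adjusted p = 0.694 with an estimated correlation), with Hba-a2 at 371.8 ± 53.9 and 267.5 ± 27.6 units and Hbb-bs at -0.45. The red blood cell median was -0.16 without WT-WD replicate 2 (adjusted p = 0.542) and -0.26 without KO-WD replicate 2 (adjusted p = 0.188). In these 7 lists no member passed over all genes. Adjusted over the list alone, 1 astrocyte and 2 microglia markers passed, and 0 in the other 5 lists.

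Neuronal groups differed by small margins, and 3 lists passed in camera with medians about as large as those of the astrocyte and ribosomal lists. Markers of CA2 and CA3 pyramidal cells had a median of 0.19 (adjusted p = 0.0444, and adjusted p = 0.618 with an estimated correlation), with Cacng5 at a log2 difference of 0.74 and Grik4, a kainate receptor subunit, at 0.27. The call was lost with a filter at 5 units (median 0.16, adjusted p = 0.0616), without WT-WD replicate 1 (0.18, 0.169), without WT-WD replicate 2 (0.15, 0.19) and without KO-WD replicate 1 (0.18, 0.307), while the median stayed near its size. It was kept without KO-WD replicate 2, with a median of 0.12. Dentate granule cell markers had a median of 0.13 (adjusted p = 0.0265, and adjusted p = 0.694 with an estimated correlation), with Lct at 0.49 and Pdzd2 at 0.42. The dentate median was 0.0416 without WT-WD replicate 1 (adjusted p = 0.536) and 0.0332 without KO-WD replicate 2 (adjusted p = 0.293), but 0.23 without KO-WD replicate 1. Monoamine and acetylcholine receptors had a median of 0.16 (adjusted p = 0.0265, and adjusted p = 0.618 with an estimated correlation), with the serotonin receptors Htr2c, which the choroid plexus also expresses strongly, at 0.65 and Htr4 at 0.59. The receptor list lost its call without WT-WD replicate 2 (median 0.11, adjusted p = 0.211) and without KO-WD replicate 1, where the median was larger (0.26, adjusted p = 0.147). It kept its call without KO-WD replicate 2, with a median of 0.0802. In these 3 lists 0 members passed adjusted over the list alone or over all genes. Markers of CA1 pyramidal cells had a median of -0.01 (adjusted p = 0.946). Presynaptic vesicle release genes had a median of 0.00 and glutamate receptor and postsynaptic density genes a median of 0.09 (both adjusted p = 0.792). The test for the presynaptic list pointed lower, against its median. Neurotrophin and CREB signalling genes had a median of -0.01 (adjusted p = 0.792), with Adcy8, a calcium-activated adenylyl cyclase, at 68.7 ± 15.2 and 38.7 ± 4.92 units, and there too the test pointed against the median. Activity-regulated early genes had a median of -0.19 (adjusted p = 0.122), with Nr4a2 at -0.51 and Fos at -0.94. In these 5 lists 0 members passed adjusted over the list alone or over all genes.

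Metabolic and inflammatory groups, which bear on diet-induced obesity, showed 1 list past the threshold. Cholesterol and fatty acid synthesis genes had a median of -0.10 (adjusted p = 0.0444, and adjusted p = 0.694 with an estimated correlation), with 19 of 24 lower. The median turned to 0.0326 without WT-WD replicate 1 (adjusted p = 0.963) and was 0.00156 without KO-WD replicate 2 (adjusted p = 0.568), but -0.21 without either of the other libraries. The call was also lost with a filter at 5 units (median -0.096, adjusted p = 0.0531), with precision weights (median -0.10, adjusted p = 0.0576) and without the intensity trend (adjusted p = 0.0569), with the median nearly unchanged. Idi1, an isomerase of the cholesterol pathway, fell adjusted over the list alone, from 10.5 ± 1.03 to 3.04 ± 0.17 units, and 0 passed over all genes. Cyp51, another enzyme of the pathway, had a log2 difference of -0.34. Insulin and IGF signalling had a median of 0.05 (adjusted p = 0.399), the AMPK and mTOR list 0.10 (adjusted p = 0.209) and the leptin, ghrelin and feeding peptide list 0.18 (adjusted p = 0.394). Inflammatory cytokines and NF-kB genes had a median of -0.16 (adjusted p = 0.716), with the interleukin receptor Il1r1 at 46.4 ± 6.37 and 73.5 ± 6.12 units. Interferon response genes had a median of -0.09 (adjusted p = 0.723). In these 5 lists 0 members passed adjusted over the list alone or over all genes.

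Of the 46 lists, 16 passed in camera with the preset correlation, 4 higher and 12 lower. With an estimated correlation 0 passed (lowest adjusted p = 0.618), and 0 passed in fry's test for 1 direction (lowest adjusted p = 0.307). Camera with an estimated correlation rests on 2 residual degrees of freedom, so this loss does not show that correlation between genes made the calls. Monoamine and acetylcholine receptors, with an estimated correlation of -0.038, under the preset 0.01, lost their call too. Whether the lists differ stays open. Fry's test for change in either direction passed 2 lists, the neighbours of Tas1r3 and the microglia markers. Without WT-WD replicate 2 the count of lists was 6, and without KO-WD replicate 2 it was 10.

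Whole libraries were about as similar between genotypes as within them. Across genes, which are not independent replicates, the Pearson correlation of log2 values averaged 0.979 within genotypes and 0.978 between them. The first 3 principal components held 37.7%, 33.5% and 28.8% of the variance. On the first, the WT-WD libraries lay at 11.2 and 30.2 and the KO-WD libraries at -7.99 and -33.4, so the genotypes did not overlap there, which chance gives in 33.3% of cases.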

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

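Coding transcripts alone, median-ratio scaling, precision weights and transcripts tested alone were chosen after seeing the data, and the other alternatives before. The same 10 genes passed under quantile normalization, no filter, a filter at 5 units, pseudocounts of 0.1 and 0.5 and median-ratio scaling. Precision weights lost the call of Cptp (limma-voom, adjusted p = 0.0715), with its log2 difference at 2.42. Choroid plexus markers (adjusted p between 1.39e-18 and 0.000322), myelin markers (2.05e-06 to 0.0257) and the endoplasmic reticulum stress list (6.81e-06 to 0.0154) kept their direction and passed under all 14 alternatives that used the preset correlation. With an estimated correlation, tested on 2 residual degrees of freedom, 0 lists passed.

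Limma without trend or robust moderation called 0 genes (0 rising, 0 falling). Without the trend 12 lists passed in camera, and the oligodendrocyte precursor (adjusted p = 0.104), CA2 and CA3 (0.099), dentate granule (0.099) and cholesterol (0.0569) lists lost their call at unchanged medians. Fitting the replicate number as a replicate block called 47 genes (28 rising, 19 falling), with Tas1r3 at -2.88 (adjusted p = 0.0473). It gained Trap1 (adjusted p = 0.017), Mpc1 (0.0458) and the choroid plexus markers F5 (0.0356) and Ttr (0.0458). It lost the oligodendrocyte precursor (camera, adjusted p = 0.082) and CA2 and CA3 lists (0.0684). The labels do not say that libraries of the same replicate number were paired, and the block leaves fewer residual degrees of freedom than the main fit. The replicate differences of the genotypes correlated at 0.04 across genes (Pearson). At adjusted p under 0.1, 13 genes passed, 4 of them falling. An unadjusted p under 0.05 with a 1.5-fold change gave 454 genes, 207 rising and 247 falling. The cause was not tested.

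Coding transcripts alone called 1 gene (1 rising, 0 falling), and 5 log2 differences reversed: Mfap2 -0.62, Tmem208 -0.52, Zranb1 -0.27, Ndc1 -0.43 and Nfxl1 1.64. The non-coding transcripts left out by construction had carried these differences. Transcripts tested alone gave 0 genes, 0 rising and 0 falling.

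Leaving out 1 library gave between 18 and 93 genes (24 without WT-WD replicate 1, 18 without WT-WD replicate 2, 93 without KO-WD replicate 1, 74 without KO-WD replicate 2), between 14 and 41 rising and between 4 and 52 falling. The lone sample was assumed to vary like the other group in limma. Cptp, Tmem208, Gm16835, Gm36445 and Gm42303 lost their call when either WT-WD library was left out, and Zranb1 and Ndc1 without WT-WD replicate 2. Gm16008, Mfap2 and Nfxl1 kept theirs in every such fit. Without WT-WD replicate 1, 5 of the 10 calls were kept, without WT-WD replicate 2, 3, and without either KO-WD library all 10. Tas1r3 ranged from -3.17 (without KO-WD replicate 2, adjusted p = 0.00942) to -2.58 (without KO-WD replicate 1, adjusted p = 0.0188). It did not pass without WT-WD replicate 1 (-2.87, adjusted p = 0.167) or without WT-WD replicate 2 (-2.88, adjusted p = 0.243). The lists past the threshold ranged from 6 (without WT-WD replicate 2) to 18 (without KO-WD replicate 1). The log2 difference of Plcb2 ranged from -1.02 (without KO-WD replicate 2) to -0.28 (without KO-WD replicate 1), Tas1r1 from -0.0667 to 0.67, Itpr3 from -0.46 to 0.12, Trpm4 from -0.0526 to 0.25 and Gng13 from -0.54 to 0.10. The median of the meningeal fibroblast list ranged from -0.96 to -0.0767, and without KO-WD replicate 2 its test turned to higher (median -0.11). The cause was not tested.

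Depth limits genes near the floor of 3 reads, such as Tas1r3 in the knockout, where a level of 0 and a few stray reads cannot be told apart.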

Other observations

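The tests of the window around Tas1r3 were written down before its result was seen, and the tests of the choroid plexus markers, the non-coding transcripts and the splits were chosen after the results were seen. Markers of neighbouring regions did not pass: striatum markers had a median log2 difference of 0.21 (camera, adjusted p = 0.135), thalamus and habenula markers -0.04 (0.723) and subiculum and cortex markers -0.16 (0.082). Among sex-linked genes, Ddx3y was at 59.99, 74.3, 57.2 and 59.01 units in WT-WD replicates 1 and 2 and KO-WD replicates 1 and 2. A single transcript of Snhg11 held between 4.55% and 5.95% of the signal. The 4 libraries split into pairs in 3 ways, 1 of which, the genotypes, gave as many as 10 genes, and the highest other split gave 4. With 3 splits this share cannot fall under 0.05.

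Genes near Tas1r3 could differ because DNA of the strain in which the allele was made was carried along around it. The share of genes with an unadjusted p under 0.05 was 3.51 times that on other chromosomes, as carried DNA would give. Without the 5 nearest tested genes on each side the ratio was still 3.13, which an effect of the allele on its immediate neighbours alone would not give. Cptp was among the genes left out, so that ratio cannot speak about an effect of the allele on Cptp itself. Cptp and Gm16008 may differ by strain and not by loss of the receptor, which was not tested for either gene. Mfap2, Ndc1 and Gm42303 also lie on chromosome 4 but outside the window, so its ratio does not speak about them. On the whole chromosome 5 of 979 genes passed over all genes, against 5 of 14694 elsewhere. Whether carried DNA reaches these 3 genes was not tested. The strain background is not given in the sources used here.

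The choroid plexus markers may reflect how much of that tissue each dissection took. They also differed between replicates: the smaller of the median replicate differences, 0.64 on the log2 scale, was 0.658 of the genotype difference, as uneven dissection would give. Replicate 1 lay above replicate 2 in both genotypes, in 17 of 19 markers in WT-WD (median 0.83) and 18 of 19 in KO-WD (median 0.64). Uneven dissection and a difference that follows the replicate number cannot be told apart here. In 11 of 17 markers of at least 10 units both KO-WD libraries lay above both WT-WD libraries, but the markers move together (estimated correlation 0.734) and uneven dissection would give the same. That count cannot speak for or against an effect of the genotype, which stays open.

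The changes of Mfap2, Ndc1, Tmem208, Zranb1 and Nfxl1 lie in the signal given to a non-coding transcript. In 5 of 5 of these genes the coding transcripts changed less than 1.5-fold in the called direction, which describes where the change lies and is no separate test of its cause. Whether the genotypes differ in splicing, in intron reads or in sequence there was not tested, since no reads were used here.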
